A study of Homo sapiens with 6 samples.

How the data were processed

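Gene expression was measured in MCF-7, an oestrogen receptor positive human breast cancer cell line. Cells were transfected with Dharmacon oligos against CtBP mRNA, or with control oligos, using the Dharmafect1 reagent. Total RNA was taken after 72 h, and biotin-labelled cRNA was hybridised to 1-colour Affymetrix arrays with 54675 probe sets. The labels give 3 CtBP knockdown samples and 3 control knockdown samples and call them biological replicates. Each sample was 1 array. The labels do not say whether the replicates came from separate transfections, so p-values measure the spread between these samples. The labels name only CtBP, so CTBP1 and CTBP2 were both reported and neither was assumed to be the only target.

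The deposited values are log2 probe set signals that the authors summarised with RMA, per the submitters' processing notes. RMA corrects background, makes the distributions of the arrays alike and summarises the probes of each probe set, so a change shared by most genes would be removed from such values. The software, its version and the annotation used with it are not given in the sources used here. The log2 scale was read from the values, which ran from 1.30 to 14.0 over the arrays, with array medians between 4.33 and 4.42. The number of arrays limits the precision. No detection calls were used, so dim probe sets were tested along with bright ones.

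Probe sets were named through the platform's gene annotation. Of the 54675 probe sets, 62 were controls, 41091 had 1 gene symbol, 1801 had several and 11721 had no gene named here. Entrez identifiers of 41037 probe sets were found in the reference gene table, and 0 symbols needed an update. Probe sets with several symbols or none were left out of the gene-level tests. Each gene was represented by its probe set with the highest mean over the 6 arrays, which gave 19775 genes, 10523 of them with more than 1 probe set. No genome sequence was used here, so no coordinates are given.

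Genes were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with the default prior) on the log2 values, with the group as the only term. Tests were 2-sided, p-values were adjusted by the Benjamini-Hochberg method over all 19775 genes, and the threshold was an adjusted p of 0.05. The prior had 5.25 degrees of freedom and the residuals 4. Standard errors are those of the moderated fit, and SDs are over the 3 arrays of a group. Differences are CtBP knockdown minus control on the log2 scale.

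The 24 gene lists, holding 849 genes, were fixed before the data were examined, as were the tests, most of the other settings and the rule for named genes. Of the list genes, 72 had no probe set of their own and were not analysed here. Lists were tested with limma's camera at its preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. Camera with an estimated correlation and limma's fry, which tests whether the genes of a list move, on balance, one way, were run beside it. Members past the threshold were counted with the adjustment over all genes and with the adjustment over the list alone. There were 29 genes in more than 1 list.

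The named genes were CTBP1, CTBP2, the 12 largest rises and 12 largest falls among genes past the threshold whose groups did not overlap, and up to 2 risen and 2 fallen members of each list with the largest difference. For a list with no member past the threshold, the member with the smallest p was named. Genes known only by a clone or locus number were passed over. Other members are given as further examples, chosen after their values were seen.

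Results were recomputed with the replicate number as a block, quantile normalization, centring on array medians, a filter on dim probe sets, other rules for combining probe sets, probe sets without the suffixes x_at and s_at, a trended robust prior, array weights, a plain 2-sample test with equal variances, and leaving out each array in turn. A further 3 were chosen after seeing the data. These were the difference between the 3' and 5' actin signals as a covariate, leaving out the array of each group with the lowest 5' actin signal, and shifting the arrays to equal means of the 9 probe sets for spiked hybridization controls.

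The comparison of CLGN with the lowest member of the stress response list met the condition, written beforehand, for setting that explanation aside. It was nevertheless counted as undecided, a choice made after the value was seen, because CLGN had been picked as the largest fall of all genes and its knockdown signals were close to background.

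The gene and list tests were first run on simulated arrays with the means and spread of these 19775 genes, in which 200 genes were changed. The fit recovered 100% of genes changed by 1 on the log2 scale and 63.0% of genes changed by 0.5, and 8.94% of its calls were on genes that had not been changed. A list shifted by 0.3 was called and 0 of the other lists were. The simulated genes were drawn independently of each other. The simulation therefore cannot show how often lists of correlated genes, as in real arrays, are called wrongly. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15, with tables read by pandas 2.3.3.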

Results

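The data were whole-genome expression profiles of MCF-7 breast cancer cells 72 h after knockdown of CtBP, with 3 arrays for CtBP knockdown and 3 for control knockdown. CtBP1 and CtBP2 are NADH-binding transcriptional corepressors, and the comparison asked which transcripts differ when they are depleted. Values are RMA log2 signals. Array medians lay between 4.33 and 4.42. Correlations between arrays were 0.993 to 0.997 within groups and 0.991 to 0.994 between groups. The first principal component, with 48.4% of the variance, separated the groups, and the second, with 23.7%, set CtBP knockdown 3 apart from the other arrays.

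CTBP1 and CTBP2 mRNA were both lower in every CtBP knockdown array than in any control array. CTBP1 was 9.10 ± 0.088 (SD, n = 3) after CtBP knockdown and 10.00 ± 0.080 in controls, a difference of -0.90 (SE 0.088, adjusted p = 0.00127) that left 53.6% of the control signal. CTBP2 was 9.79 ± 0.040 after knockdown and 10.66 ± 0.023 in controls, a difference of -0.86 (SE 0.077, adjusted p = 0.000811) that left 54.9%. Of the 4 CTBP1 probe sets, 3 were lower and left 49.4% to 53.6%. All of these 3 end in s_at or x_at. Of the 6 CTBP2 probe sets, 5 were lower and left 52.7% to 61.3%. Without s_at and x_at probe sets CTBP2 still differed by -0.85 (limma adjusted p = 0.00172). The remaining probe set of each gene differed by -0.04 for CTBP1 and 0.05 for CTBP2. For CTBP2 it lay below the array medians, and for CTBP1, at 4.82 and 4.86, a little above them. With the array of lowest 5' actin signal left out of each group, CTBP1 differed by -0.81 and missed the threshold (adjusted p = 0.0542). Over the other settings tried its adjusted p ran from 2.91e-05 to 0.893, the latter for that remaining probe set alone.

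Knockdown of CtBP changed 1285 of 19775 genes, or 6.50%, of which 809 rose and 476 fell. Changes of at least 1.5 times were seen in 427 genes, and 34 rose and 25 fell by at least 2 times. The median absolute difference of the changed genes was 0.51, beside a median residual SD of 0.12. All 1285 changed genes had groups that did not overlap, as did 28.4% of all genes, where chance gives 10%. The higher share, 63.0%, depended on how the arrays were scaled: shifting them to equal spiked hybridization controls gave 332 higher and 859 lower genes, a higher share of 27.9%, and moved the median difference of all genes from 0.00 to -0.12. That shift lowers every gene alike, by 0.12, while the smallest difference of a changed gene was 0.31, so it could turn none of them. The difference of 0.12 between the groups in the spiked controls was itself not established (exact 2-sided permutation test, p = 0.2, where 3 against 3 allows no p under 0.1). Of their 9 probe sets, 0 passed the threshold in a limma fit over all probe sets. All 1285 genes kept their direction with quantile normalization and with centring on array medians. The array medians, 4.33 to 4.42, lay closer together than the smallest difference of a changed gene, so centring could turn none of them either. Quantile normalization repeats a step that RMA had already taken, so the directions kept there say little. The number of calls also depended on single arrays. It was 250 without control 1, 261 without control 2, 879 without control 3, 392 without CtBP knockdown 1, 447 without CtBP knockdown 2 and 1961 without CtBP knockdown 3. Of the 80 named genes past the threshold, 36 kept their call in each of these 6 fits. All 80 kept their direction, which was fixed in advance because their groups did not overlap.

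The largest rise was that of ANXA1, a calcium-dependent phospholipid-binding protein, from 5.31 ± 0.040 to 7.72 ± 0.17 (SD, n = 3), a difference of 2.41 (SE 0.10, adjusted p = 2.55e-05). Its relative ANXA3 rose by 1.83 (SE 0.11). ERP27, a protein of the endoplasmic reticulum, rose by 2.11 (SE 0.20), SERPINB5, which encodes maspin, by 2.07 (SE 0.21), and GBP1, an interferon-inducible GTPase, by 2.04 (SE 0.14). RASGRP1, an activator of Ras, rose by 1.72, ACP3, the prostatic acid phosphatase, by 1.64, and TP53I3, a p53-induced oxidoreductase, by 1.63. The death receptor gene FAS and the caveolin gene CAV2 both rose by 1.57, the neuropeptide gene GAL by 1.54 and LINC01213, a long non-coding RNA, by 1.38. SERPINB5 (3.79) and CAV2 (3.57) had control means below all array medians, and ERP27 and RASGRP1 (both 4.52) had control means close to them, so these rises start near background and their sizes and order are uncertain. All 12 kept their call when any 1 array was left out. ACP3 was called on 1 of its 3 probe sets, ANXA1, GAL and SERPINB5 on 1 of 2, and FAS on 4 of 5. Without probe sets of the s_at and x_at kinds, ACP3 differed by -0.06 and FAS by -0.24, neither past the threshold, and CAV2 by 0.42, which passed (adjusted p = 0.0319).

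The largest fall was that of CLGN, which encodes calmegin, a chaperone of the endoplasmic reticulum. Its signal went from 8.59 ± 0.062 to 4.53 ± 0.94 (SD, n = 3), a difference of -4.06 (SE 0.36, adjusted p = 0.000811). It rests on 1 probe set, and its knockdown values of 3.63, 4.46 and 5.49 lay around the array medians of 4.33 to 4.42, where signals are close to background and the size of a difference is uncertain. LAMP3, a lysosome-associated membrane protein, fell by 2.18 (SE 0.11), the potassium channel subunit gene KCNE4 fell by 2.12 (SE 0.16), and UBE2QL1 fell by 1.65 (SE 0.11). The knockdown mean of LAMP3, 4.29, also lay below the array medians, and those of CFAP263 (4.63) and SMOC2 (4.61) lay close above them, so the sizes of these falls are uncertain too. BEX2 signal was 2.84 times as high in controls as after knockdown. NIBAN1 fell by 1.48, CFAP263 by 1.44, the non-coding RNA EPB41L4A-AS1 by 1.31 and SMOC2, a matricellular protein gene, by 1.31. DDIT3, the stress-induced transcription factor CHOP, fell by 1.25 (SE 0.11), the immediate early gene EGR1 fell by 1.23 and LINC01503 by 1.20. Of these 12, EGR1 lost its call without control 1 (-1.15, adjusted p = 0.0505) and SMOC2 without control 1 (-1.31, adjusted p = 0.0698), control 2 (-1.25, adjusted p = 0.0685) or CtBP knockdown 2 (-1.27, adjusted p = 0.0648), and the other 10 kept theirs when any 1 array was left out. All 3 KCNE4 probe sets, both NIBAN1 probe sets and 2 of 3 for EGR1 were called lower, but 1 of 2 for each of UBE2QL1, EPB41L4A-AS1 and SMOC2. SMOC2 differed by -0.10 without the s_at and x_at probe sets (adjusted p = 0.803) and by -0.70 with the mean of its probe sets (adjusted p = 0.0696). Of the 66 named genes past the threshold that have other probe sets than s_at and x_at, leaving out CTBP1 and CTBP2, 11 missed the threshold on those. With the mean of probe sets 23 of 78 missed it.

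**Figure D1:**
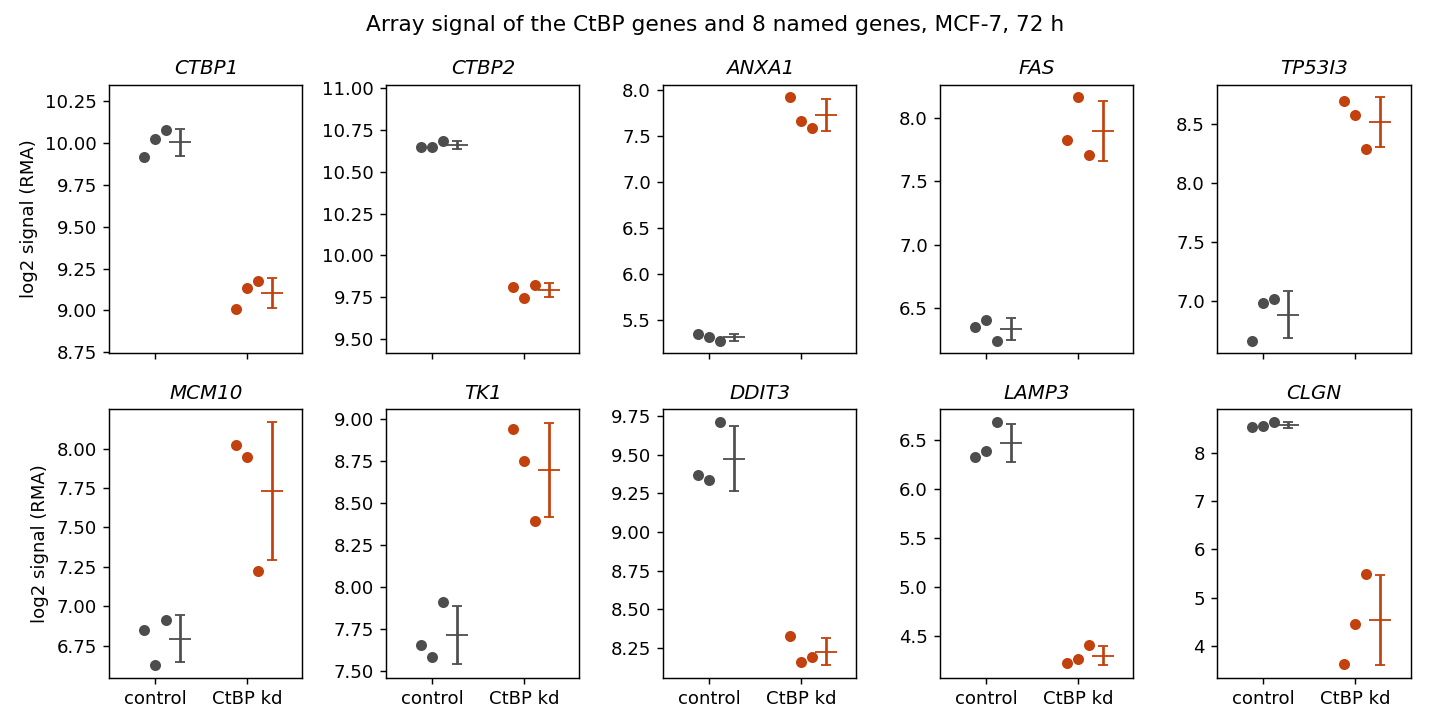
RMA log2 signal (vertical axes, scaled separately for each gene) in the 3 control and 3 CtBP knockdown arrays, one point per array, with the mean and SD of each group beside the points. CTBP1 and CTBP2 fell by 0.90 and 0.86, ANXA1 rose by 2.41 and CLGN fell by 4.06, and in each of the genes drawn the groups do not overlap.

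Genes of DNA replication were higher after CtBP knockdown. Of the 54 measured members, 21 rose, 1 fell and 32 did not pass; adjusted over the list alone, 37 rose and 1 fell. The list median was 0.41 (camera adjusted p = 1.41e-15), and the adjusted p with an estimated correlation was 0.397. TK1, the S-phase thymidine kinase, rose by 0.98 (SE 0.15), and MCM10, an initiation factor, by 0.94 (SE 0.19), with both TK1 probe sets and all 3 MCM10 probe sets higher. TK1 kept its call whichever array was left out, and MCM10 kept it in 1 of the 6 such fits, without CtBP knockdown 3. Other rises were UHRF1 at 0.90, PCNA, the sliding clamp, at 0.88, GINS2 at 0.87 and MCM5 at 0.83. DUT, a dUTPase, fell by 0.38, with 2 of its 3 probe sets lower. The count of risen members was 6 without control 1, 9 without control 2, 10 without CtBP knockdown 1, 10 without CtBP knockdown 2 and 35 without CtBP knockdown 3, while the median stayed between 0.33 and 0.50. With both arrays of low 5' actin signal left out, 0 members passed, and the median was 0.36.

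Of 37 genes of homologous recombination and the Fanconi pathway, 7 rose, 0 fell and 30 did not pass, with a median of 0.24 (camera adjusted p = 2.70e-05, and an adjusted p of 0.397 with an estimated correlation); adjusted over the list alone, 18 rose and 1 fell. RAD54B rose by 0.56 (SE 0.11) and FANCI by 0.56 (SE 0.088), with all 3 FANCI probe sets higher. BRCA1, singled out after its value was seen, differed by 0.52 and missed the threshold (adjusted p = 0.0566). The number of risen members was 0 without control 1 or control 2, 1 without CtBP knockdown 1 or 2, 2 without control 3 and 13 without CtBP knockdown 3. It was 1 with the actin covariate and 2 with the replicate block, and with arrays shifted to equal spiked controls it was 1, with a median of 0.11. Among 43 genes of the damage checkpoint and other repair, 6 rose and 1 fell (8 and 6 adjusted over the list alone), and the list did not pass (adjusted p = 0.0707), but passed without CtBP knockdown 3 (adjusted p = 0.0344), with array weights (adjusted p = 0.0356) and with fry (adjusted p = 0.0311). POLH, a translesion polymerase, rose by 0.91 (called on 1 of 6 probe sets), TIPIN, a replication fork protein, rose by 0.61, and the nuclease gene ERCC4 fell by 0.51. No TIPIN or ERCC4 probe set was called by itself, and TIPIN kept its call in 1 of the 6 fits that left out an array. In contrast to replication genes, the 64 mitosis genes had a median of 0.00, with 2 risen, 5 fallen and 57 that did not pass (10 and 7 adjusted over the list alone; camera adjusted p = 0.776). SPC24, a kinetochore gene, rose by 0.73 and MELK by 0.41, while TOP2A, a topoisomerase gene, fell by 0.66 and HMMR by 0.47.

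Of 38 p53 targets and cell cycle inhibitors, 13 rose, 0 fell and 25 did not pass; adjusted over the list alone, 21 rose and 1 fell. The median was 0.30 (camera adjusted p = 1.83e-09), and this was the 1 list that also passed with an estimated correlation (adjusted p = 0.0422). Besides TP53I3 and FAS, CDKN2B, an inhibitor of cyclin-dependent kinases, rose by 0.96, PLK2 by 0.87, TIGAR by 0.85, GADD45A by 0.72, SESN1 by 0.71 and the apoptosis gene BAX by 0.53. CDKN1A, which encodes p21, and MDM2 differed by 0.26 and 0.24 and did not pass; both were singled out after their values were seen. The count of risen members lay between 8, without control 2, and 14, without CtBP knockdown 3. It was 3 with both arrays of low 5' actin signal left out.

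Genes of the unfolded protein and integrated stress responses were lower. Of 32 members, 16 fell, 1 rose and 15 did not pass; adjusted over the list alone, 23 fell and 3 rose. The median was -0.43 (camera adjusted p = 6.61e-11), and the adjusted p with an estimated correlation was 0.277. Besides DDIT3, the amino acid transporter subunit gene SLC3A2 fell by 1.03 (SE 0.18), SEL1L, of endoplasmic reticulum-associated degradation, by 0.79, the cystine transporter gene SLC7A11 by 0.77 and HSPA5, which encodes the chaperone BiP, by 0.64. The transcription factor gene ATF3 rose by 0.84 (SE 0.15), called on 1 of 3 probe sets, and differed by 0.02 without the s_at and x_at probe sets. ATF4 and ASNS, singled out after their values were seen, differed by -0.31 and -0.95 and did not pass. The count of fallen members was 4 without control 1, 5 without control 2, 9 without CtBP knockdown 1, 10 without CtBP knockdown 2 and 10 without control 3. It was 1 with both arrays of low 5' actin signal left out, where the median was -0.34.

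Cholesterol synthesis genes were higher. Of 23 measured, 5 rose, 0 fell and 18 did not pass, with a median of 0.29 (camera adjusted p = 1.55e-06, and an adjusted p of 0.277 with an estimated correlation); adjusted over the list alone, 12 rose. ACAT2, an early enzyme of the pathway, rose by 0.95 (SE 0.20). The sterol desaturase gene SC5D rose by 0.77 (SE 0.095) on 1 of its 2 probe sets, and the other differed by -0.15. HSD17B7 rose by 0.73 and EBP by 0.55. The count of risen members was 2 without control 1, control 2, CtBP knockdown 1 or CtBP knockdown 2.

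Other metabolic lists moved less. None of the 47 genes of oxidative phosphorylation and the TCA cycle passed with limma, over all genes or over the list alone, yet the list did, with a median of 0.14 (camera adjusted p = 0.00189, and 0.397 as the adjusted p with an estimated correlation); NDUFA2, a complex I subunit, differed by 0.31 (adjusted p = 0.0520). With arrays shifted to equal spiked controls the list median was 0.01, with 24 of 47 members above 0 in place of 36, beside a median of -0.12 for all genes (camera adjusted p = 0.0201). At an unadjusted p under 0.05 there were 14 such members, and a plain 2-sample test with adjustment gave 0. Of 23 hypoxia response genes, 4 fell and 1 rose (6 and 1 over the list alone; median -0.16, camera adjusted p = 0.00457, and 0.397 with an estimated correlation). The collagen hydroxylase gene P4HA1 fell by 0.81 on 1 of its 2 probe sets, the other at 0.04, DDIT4 fell by 0.62, and ANKRD37 rose by 0.41. The hypoxia list did not pass without the s_at and x_at probe sets (adjusted p = 0.400) or with fry (adjusted p = 0.0998). Glycolysis genes, 24 in number, did not pass as a list (median -0.09, adjusted p = 0.0707): 4 fell and 1 rose (6 and 3 over the list alone), among them PDK1 at -0.61, PFKL at -0.46 and the pyruvate kinase gene PKM at 0.89. Without control 3 the glycolysis list passed (adjusted p = 0.0414). Of 37 lysosome and autophagy genes, 3 fell and 1 rose (6 and 3 over the list alone), with a median of -0.11 and a camera adjusted p of 0.0390. NEU1 and ATG2B fell by 0.49 and 0.44 and GLA, which encodes alpha-galactosidase, rose by 0.45; no probe set of NEU1, ATG2B or GLA was called by itself. This list did not pass without CtBP knockdown 1 (adjusted p = 0.113) or control 2 (adjusted p = 0.0561), nor with an estimated correlation (adjusted p = 0.401), and its adjusted p ran from 0.0121 to 0.488 over all settings. The 35 translation and ribosomal protein genes had a median of -0.05 and no member past the threshold, over all genes or over the list alone (camera adjusted p = 0.0359, and 0.591 with an estimated correlation). At an unadjusted p under 0.05 there were 3, and 0 by the plain 2-sample test with adjustment. EEF2, an elongation factor, differed by -0.35 (adjusted p = 0.0555). It passed with some other settings, and its adjusted p ran from 0.00375 to 0.214 over them. Without CtBP knockdown 2 or control 2 the translation list did not pass, with adjusted p of 0.10 and 0.0561, in a range of 0.00229 to 0.591 over all settings.

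Epithelial and lineage genes changed in both directions, and none of their lists passed in the camera test at its preset correlation. Of 41 adhesion and polarity genes, 7 rose and 2 fell (9 and 3 over the list alone; median 0.11, camera adjusted p = 0.0521). DSG2, a desmosomal cadherin, rose by 0.81 and LLGL2, a polarity gene, by 0.80, while DSP, which encodes desmoplakin, fell by 0.57 and CLDN12 by 0.53. The list passed without control 3 (adjusted p = 0.0370), without CtBP knockdown 1 (adjusted p = 0.0277) and with several other settings. Its adjusted p ran from 0.0157 to 0.397 over all settings. CDH1, the E-cadherin gene, singled out after its value was seen, differed by -0.23 and did not pass. Of 40 mesenchymal genes, 3 rose and 2 fell (3 and 3 over the list alone; median -0.00, adjusted p = 0.960), with CCN1 at 0.58, VIM, which encodes vimentin, at 0.57, TGFBI at -0.76 and FN1, which encodes fibronectin, at -0.47. FN1 differed by -0.12 without the s_at and x_at probe sets and missed the threshold. Among 24 luminal genes, 2 rose and 3 fell (2 and 3 over the list alone; median -0.03, adjusted p = 0.353): the trefoil factor gene TFF3 fell by 0.90, SPDEF fell by 0.40, NAT1 rose by 0.48 and CA12 by 0.37. No luminal gene was called without control 1, control 2 or CtBP knockdown 1. Among 18 basal and myoepithelial genes, 5 rose and 0 fell (5 and 1 over the list alone; median 0.07, adjusted p = 0.125), led by CAV2 and by ACTA2, smooth muscle actin, which rose by 1.13 (SE 0.11) on 1 of 3 probe sets. The basal list passed with arrays shifted to equal spiked controls (adjusted p = 0.0250) and with fry (adjusted p = 0.0126), in a range up to 0.738 over all settings.

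Signalling lists did not pass in that test either. Oestrogen response genes, 41 in number, had 4 risen and 3 fallen members (7 and 7 over the list alone; median -0.10, adjusted p = 0.199), but 1 and 6 with arrays shifted to equal spiked controls, and 1 and 1 without control 1, control 2 or CtBP knockdown 2. The small heat shock gene HSPB8 rose by 0.85 and PRSS23 by 0.57, and the cationic amino acid transporter gene SLC7A2 fell by 0.76 and EGR3 by 0.43. HSPB8 was called on 1 of 2 probe sets and differed by 0.10 without the s_at and x_at probe sets (adjusted p = 0.641), and PRSS23 was called on 1 of 4. ESR1, the oestrogen receptor gene, singled out after its value was seen, differed by -0.15 and did not pass. Of 44 interferon response genes, 5 fell and 1 rose (6 and 2 over the list alone; median -0.05, adjusted p = 0.0937), with IFIT1 at -0.88, HERC6 at -0.59 and the antigen peptide transporter gene TAP1 at 0.61. Both IFIT1 means lay below the array medians, no IFIT1 probe set was called by itself, and its call held in 2 of the 6 fits that left out an array. The interferon list passed without control 2 (adjusted p = 0.0289), and its adjusted p ran up to 0.397 over all settings. Of 26 TGF beta and BMP targets, 2 rose and 3 fell (4 and 3 over the list alone; median 0.05, adjusted p = 0.267), including TGFB2 at 0.72 and the receptor gene TGFBR2 at 0.53, and, besides TGFBI, BHLHE40 at -0.55. TGFB2 was called on 1 of 5 probe sets and TGFBR2 on 1 of 2, and with the mean of probe sets they were at 0.23 (adjusted p = 0.0962) and 0.29 (adjusted p = 0.140). The control mean of TGFB2 also lay below the array medians. Of 22 Notch and Wnt targets, 4 rose and 0 fell (5 and 1 over the list alone; median 0.04, adjusted p = 0.186), led by HEY2 at 0.73 and NOTCH3 at 0.62. NOTCH3 was called on 1 of 2 probe sets, was at 0.22 with their mean (adjusted p = 0.233) and kept its call in 2 of the 6 fits that left out an array. No Notch or Wnt target was called without control 1 or without control 2. The list passed with fry (adjusted p = 0.0311). Of 22 stem cell associated genes, 3 rose and 0 fell (6 and 2 over the list alone; median 0.10, adjusted p = 0.132), led by the efflux transporter gene ABCG2 at 0.88. Among 31 partners of CtBP in repressor complexes, 2 fell and 0 rose, over all genes and over the list alone (median -0.06, adjusted p = 0.0707): HDAC1, a histone deacetylase gene, at -0.48 and HIPK2 at -0.44, the latter with no probe set called by itself. The partners passed over bright probe sets alone (adjusted p = 0.0412) and with a trended robust prior (adjusted p = 0.0433), in a range up to 0.890.

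Markers of other cell types did not move as lists. CD8A, at 0.39, was the 1 of 20 leukocyte genes past the threshold (3 rose over the list alone; median -0.06, adjusted p = 0.776). None of 20 fibroblast and endothelial genes passed with limma, over all genes or over the list alone (median 0.02, adjusted p = 0.716); 4 had an unadjusted p under 0.05 and 0 passed in the plain 2-sample test with adjustment. COL3A1 differed by 0.29 (adjusted p = 0.0918), although 1 of its 5 probe sets was called higher by itself.

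Single list members rested on the choice of probe sets, the adjustment and the arrays to different degrees. At probe set level, where more tests are adjusted for, no probe set was called for TIPIN, GLA, ANKRD37, MELK, CD8A, ATG2B, HIPK2, PFKL, NEU1, ERCC4, TGFBI or IFIT1. TIPIN, GLA, MELK, CD8A, NEU1, TGFBI and IFIT1 have 1 probe set, so for them only the adjustment and the prior differed. The same holds for NEU1 and TGFBI with the mean of probe sets. With the mean of probe sets, the named genes that missed the threshold were PKM, ATF3, SC5D, SPC24, TGFB2, NOTCH3, VIM, PRSS23, TGFBR2, ANKRD37, CA12, SPDEF, ATG2B, HIPK2, FN1, NEU1, ERCC4, HERC6, PDK1, TOP2A, TGFBI, P4HA1 and SMOC2. Of the 6 fits that left out an array, DUT kept its call in 0. ANKRD37, BHLHE40, CA12, GLA, HDAC1, HIPK2, MCM10, MELK, NEU1, PFKL, RAD54B, SPDEF and TIPIN kept it in 1. ACAT2, ATF3, ATG2B, CCN1, CD8A, DSP, EGR3, ERCC4, HMMR, IFIT1, NOTCH3, P4HA1, PDK1, PKM, SPC24, TFF3 and TGFBI kept it in 2. Those that kept it in 3 were FN1, HEY2, NAT1, PRSS23, SMOC2 and TGFB2.

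Over the 24 lists, 5 passed as higher and 4 as lower with camera at its preset correlation, and 1, the p53 targets, passed with an estimated correlation. In each of the 24, the count of members past the threshold was lower, or equal, without control 1, control 2, CtBP knockdown 1 or CtBP knockdown 2. Leaving out 1 of these arrays removed every call, besides those given above, for the partners, glycolysis and leukocyte lists with any of the 4, for the lysosome list without control 1, control 2 or CtBP knockdown 1, for the mesenchymal list without control 1 or control 2, and for the checkpoint and mitosis lists without control 1. The balance of calls also depended on the scaling. With arrays shifted to equal spiked controls, risen and fallen members numbered 15 and 1 for replication, 11 and 0 for p53 targets, 1 and 18 for the stress responses and 3 and 0 for cholesterol. They were 0 and 5 for hypoxia, 0 and 5 for lysosome, 1 and 5 for glycolysis, 1 and 3 for the checkpoint list, 1 and 8 for mitosis, 3 and 3 for adhesion and polarity and 1 and 4 for mesenchymal genes. They were 0 and 3 for luminal genes, 3 and 1 for basal, 1 and 7 for interferon, 2 and 3 for TGF beta and BMP, 2 and 0 for Notch and Wnt, 2 and 2 for stem cell, 0 and 4 for the partners, 0 and 0 for leukocyte and 0 and 1 for translation genes. Camera compares the mean test statistic of the members with that of the other genes. For the mitosis, leukocyte and mesenchymal lists it gave a downward direction. The median differences of these lists were also below 0, while their mean differences were above 0. With arrays shifted to equal spiked controls, medians turned below 0 for the epithelial, basal, stem cell, checkpoint, TGF beta and BMP, Notch and Wnt, and fibroblast and endothelial lists, beside the median of all genes of -0.12, and the medians of the 9 lists past the threshold kept their signs, with oxidative phosphorylation close to 0. The 3' minus 5' actin signal, a measure of RNA integrity, was 2.24, 0.55 and 1.32 in CtBP knockdown 1, 2 and 3 and 0.68, 0.75 and 1.73 in control 1, 2 and 3. Its means differed by 0.32 (exact 2-sided permutation test, p = 0.7, where 3 against 3 allows no p under 0.1). The 3' minus 5' GAPDH signal lay between 0.15, in control 1, and 0.20, in control 2, so it did not show the spread seen with actin.

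**Figure D2:**
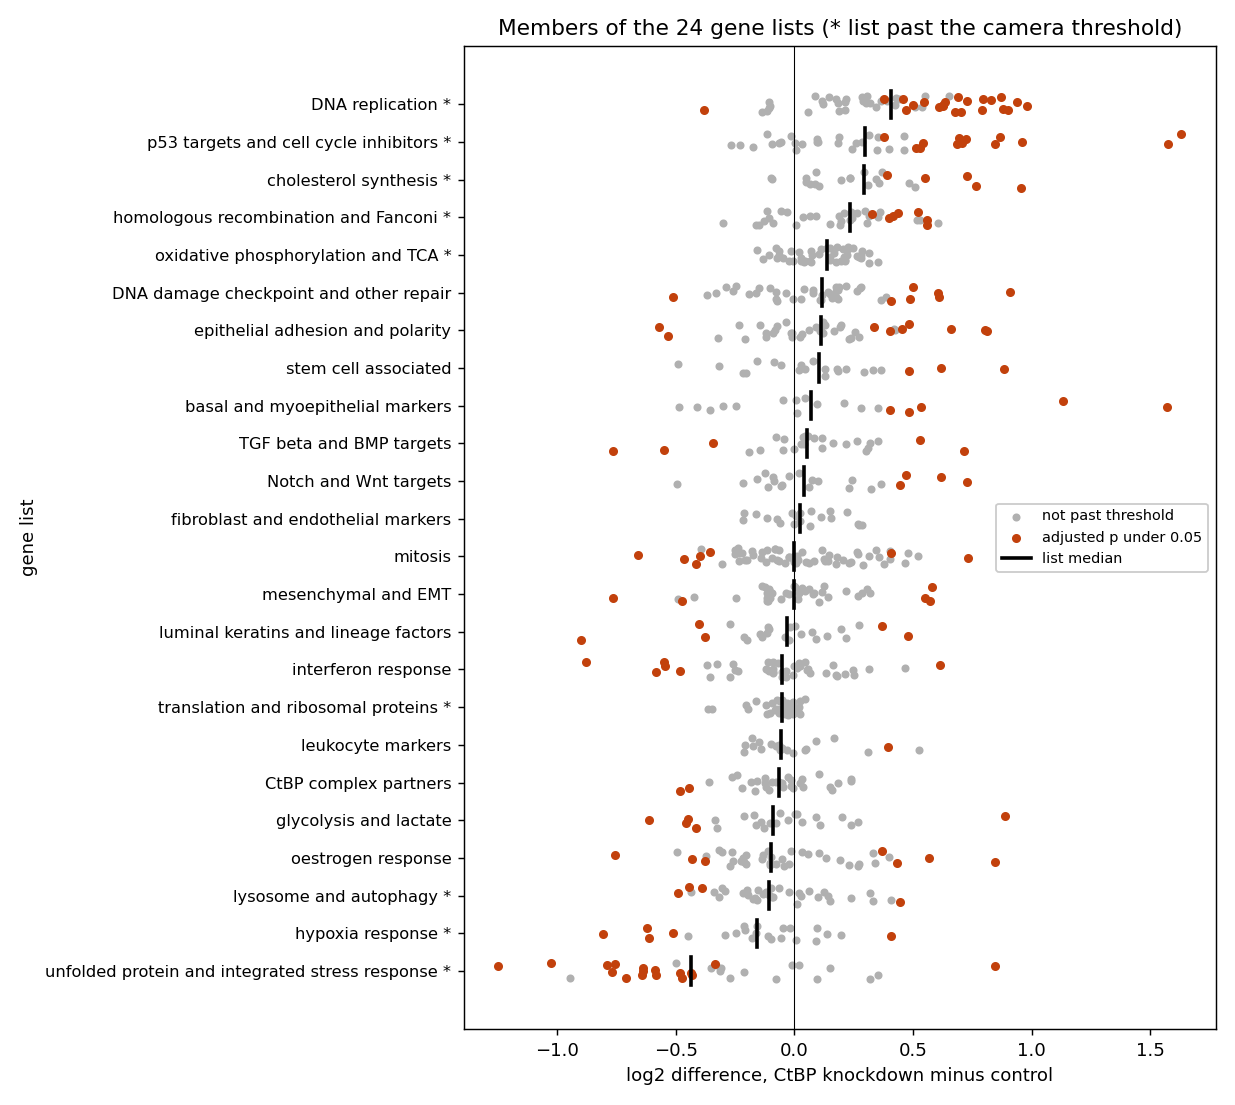
Log2 difference of CtBP knockdown minus control (horizontal axis) for the measured members of the 24 gene lists (rows, ordered by median), 1 point per gene, with members at an adjusted p under 0.05 in orange, other members in grey and the list median as a black bar. DNA replication genes, with a median of 0.41, lie highest, and unfolded protein and integrated stress response genes, with a median of -0.43, lie lowest.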

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

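Of 13522 probe sets with no single gene name here, which the gene-level comparison does not use, 188 passed the threshold between CtBP knockdown and control in a limma fit over all probe sets. Of these, 131 were higher and 57 lower, and the control arrays are the background they were tested against. Their genes were not analysed here, and no explanation was tested.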

How the results depend on the processing

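The 3 alternatives on actin and on spiked controls were chosen after seeing the data. The replicate block gave 688 changed, 427 higher and 261 lower genes. The values gave no sign that replicate numbers pair the samples. Deviations of same-numbered arrays correlated at -0.0976, 0.111 and -0.0483 for numbers 1, 2 and 3. CtBP knockdown 1, 2 and 3 correlated best with control 3, 1 and 2 (0.212, 0.145 and 0.0894), so not every sample correlated best with its own number. Correlations this weak, with 3 arrays per group, cannot exclude that same-numbered samples shared a day or culture. Probe sets above median brightness gave 2132 (1314 higher, 818 lower), with fewer genes tested. The mean of probe sets gave 263 changes of at least 1.5 times and 0.000414 for ATG2B, and the most variable probe set 658. Without x_at and s_at probe sets there were 849 (535 higher, 314 lower), and other probe sets stood for CTBP1 at -0.0412 (adjusted p = 0.893), ACP3 at -0.0632, FAS at -0.24, SC5D at -0.15 and P4HA1 at 0.0392. A trended robust prior gave 2307 (1432 higher, 875 lower), array weights 2726 (1615 higher, 1111 lower), and a plain 2-sample test, which borrows no spread between genes, 82 (54 higher, 28 lower), 39 of them by 1.5 times, and no list value. The actin covariate gave 647 (428 higher, 219 lower). Leaving out both arrays of low 5' actin signal, with 4 arrays remaining, gave 53 (36 higher, 17 lower), all 53 by 1.5 times, and CTBP1 at -0.81. Spiked-control scaling gave 332 higher and 859 lower. An estimated correlation left 1 list. Leaving out 1 array gave 250 to 1961 changed, 165 to 1116 higher, 82 to 845 lower and 226 to 611 by 1.5 times, and 8 to 11 lists; CTBP1 stayed between -0.94 and -0.85 and CTBP2 between -0.88 and -0.84. Beyond what fewer samples, fewer genes or other probe sets bring, the cause was not tested. Over all alternatives the named genes gave 1114 values on the same side of the threshold in the same direction, 388 that missed it and 15 that passed it. The 5 values above for ATG2B, ACP3, FAS, SC5D and P4HA1 were of opposite sign, as were 2 for genes not past the threshold, NDUFA2 (-0.0996) and COL3A1 (-0.175), both without x_at and s_at probe sets. Lists gave 439, 24 and 17, with 0 calls lost for p53 targets, 9 for lysosome, 7 for translation and 3 for hypoxia. Dim probe sets have signals near background, which limits what can be called there.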

Other observations

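The tests of the tubulin, annexin and tRNA synthetase families, of the share of dividing cells, of scaling as the whole cause and of the ATF4 programme were chosen after their results, or related ones, had been seen. The families were picked for their changes, so list tests computed on them are void and their sizes and counts are given instead. A permutation test of the synthetases, given below with the second pattern, shares that limit. Tubulin genes, which encode the subunits of microtubules, were higher after CtBP knockdown: 7 of 15 rose, 14 differences were above 0 and the median was 0.29. TUBB2A rose by 1.38 (SE 0.16), TUBA1A by 0.87 and TUBB6 by 0.84. Of 11 annexin genes, 4 rose and all 11 differences were above 0, with a median of 0.18. Besides ANXA1 and ANXA3, ANXA2 rose by 0.59 and ANXA4 by 0.45. The family was singled out because of ANXA1 and ANXA3, and the other 9 members had a median of 0.08. Tubulins without TUBB2A had a median of 0.27, but TUBA1A, TUBB6 and other risen members prompted the choice as well. With arrays shifted to equal spiked controls, where the median of all genes was -0.12, the medians were 0.16 for tubulins and 0.06 for annexins, with 12 and 6 members above 0. Quantile normalization and centring gave 0.26 and 0.29 for tubulins and 0.17 and 0.18 for annexins.

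Cytosolic aminoacyl-tRNA synthetase genes, many of which are known targets of the transcription factor ATF4, were lower: 5 of 17 fell, 0 rose and the median was -0.27. WARS1 fell by 0.87, SARS1 by 0.83, YARS1 by 0.60 and AARS1 by 0.58. The 15 mitochondrial synthetase genes had a median of 0.03, with 1 risen and 1 fallen. KARS1 and GARS1, counted here as cytosolic, also serve mitochondria. The median of the cytosolic genes was -0.40 with spiked-control scaling, -0.29 with quantile normalization and -0.27 with centring. Spiked-control scaling lowers every gene and centring hardly moves them, so neither could bring it above 0. Quantile normalization repeats a step of RMA. The median of the mitochondrial genes was -0.10 with spiked-control scaling, beside -0.12 for all genes.

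The first pattern is that DNA replication genes were higher, with a median of 0.41. With the actin covariate the median was 0.37, and the list still passed (camera adjusted p = 2.17e-14). With an estimated correlation and no covariate it did not pass (adjusted p = 0.397). The mean actin signal differed between the groups by only 0.32, beside array values from 0.55 to 2.24. The covariate therefore had little room to move the median, and GAPDH did not show the spread of actin. RNA integrity as the cause stays undecided. For scaling of the arrays as the whole cause, the spiked controls were examined. They differed by 0.12 between the groups and by at most 0.25 between any knockdown and control array. Shifting the arrays to equal spiked controls left a median of 0.28, and scaling may account for part of the size. The median left was 0.693 of the unshifted one, short of the share written beforehand for setting scaling aside. That earlier test was therefore undecided. The test of scaling as the whole cause was chosen later, after related values had been seen, so no conclusion is drawn from it. Hybridization controls in RMA values also cannot show a change shared by most genes that RMA removed. A larger share of dividing cells overall would raise mitosis genes as well, yet the median of replication genes exceeded that of mitosis genes by 0.41 (95% bootstrap interval over genes 0.28 to 0.54). That interval treats genes as independent replicates, which they are not, and leaves out the spread between arrays. A shift within the cell cycle or in transcription of these genes after CtBP knockdown stays open and was not tested.

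The second pattern is that unfolded protein and integrated stress response genes were lower, with a median of -0.43. The actin covariate left -0.41, but it had little room to move this median either, so RNA integrity as the cause stays undecided. With an estimated correlation and no covariate the list did not pass (adjusted p = 0.277). Scaling would need spiked controls lower after knockdown by about the list median, but the lowest difference of any knockdown and control array was -0.0324. Shifting the arrays to equal spiked controls lowered the list, with all genes, to -0.56. The limits of the spiked controls given for the first pattern hold here too. A hypothesis is that the ATF4 programme may be less active after CtBP knockdown. Cytosolic synthetase genes, none of which is on the list, were lower than mitochondrial ones by a mean of -0.31, the direction that hypothesis needs. A permutation test across genes gave a 2-sided p of 0.00842 (100000 resamples). Genes are not independent replicates, and the families were chosen after related values were seen. Neither the direction nor that p is therefore independent support for the hypothesis. A difference between the transfections in stress or nutrient supply stays open and was not tested.

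The third pattern is that CLGN differed by -4.06, far beyond the -0.90 and -0.86 of CTBP1 and CTBP2. Whether it belongs to the fall of the stress response list stays open. CLGN lay 7.73 of its standard errors below DDIT3, the lowest list member, but it was singled out as the largest fall of all genes, a shared cause allows falls of unequal size, and its knockdown signals were close to background. Whether 1 faulty probe set is the cause stays open because 0 other CLGN probe sets were measured. A direct effect of the CtBP oligos on CLGN may be possible too, and it was not tested because their sequences were not used here.

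With the samples regrouped in all 10 splits into 3 and 3, 1 split, the real one, gave as many changed genes (1285), genes higher (809), genes lower (476) and changes of at least 1.5 times (427), with 0 in every other split. For gene lists, 1 split, the real one, gave as many as 9, and the highest other split gave 6. The other splits gave 5, 4, 6, 2, 1, 1, 0, 3 and 1 lists. Camera at its preset correlation thus called lists in groupings where 0 genes passed, so its small adjusted p-values call for caution. The 10 splits are too few for a share under 0.05.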
